A study of Homo sapiens with 9 samples.

How the data were processed

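RNA sequencing of 9 libraries of the human neuroblastoma cell line NLF was analysed from the count and FPKM tables that the authors deposited. Per the labels, the cells had received a non-targeting siRNA (siNTC), an siRNA against TBX2 (siTBX2) or one against TBX2-AS1 (siTBX2-AS1) for 48 hours, with 3 biological replicates in each of the 3 groups. Total RNA was depleted of ribosomal RNA and made into stranded libraries. Per the submitters' processing notes, the authors used FastQC, STAR 2.4.2a, StringTie 1.3.3 and the genome build hg19. The annotation, the counting program, the use of strand in counting and the siRNA sequences were not given in the sources used here.

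The first table deposited by the authors holds expected counts, estimates of reads per gene, as whole numbers that are not scaled to depth, so no rounding was needed. For 448 genes with one annotated transcript, 74.9% of the values had the same ratio of count to FPKM times length within 0.02 on the log2 scale, against 18.8% for 8059 genes with several transcripts, which ties these counts to the coverage that StringTie computed. The second table deposited by the authors holds FPKM, fragments scaled to transcript length and to mapped fragments, and was used as an alternative scale. Both tables had 57757 gene IDs and no lines of totals. Symbols were found for 52286 IDs, 39497 in the table of gene names and 12789 in GENCODE release 29, which cover 95.02% of the counts; 5471 IDs had none, and 47 were copies in the pseudoautosomal region. Positions were looked up by gene ID in GENCODE release 29 on GRCh38, which is not the build of the files.

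Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries were scaled with TMM, and 18367 genes were tested with quasi-likelihood F tests (robust fit) on all 9 libraries, with siTBX2 against siNTC, siTBX2-AS1 against siNTC and siTBX2-AS1 against siTBX2 as comparisons. Adjusted p values are those of Benjamini and Hochberg, and genes with an adjusted p under 0.05 are called rose or fell. SE is that of the log2 fold change. The targets were also compared by an exact two-sided permutation test on CPM. Depth was 31894280 to 51434090 counts per library. For replicate pairs of a group, the chi-square per gene for counting error alone was 46.9 to 74.3, where 1 is given by counting error. Separate samples exceed 1 in advance, so this gives the size of the replicate spread and tests nothing.

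Named genes followed a rule. It took TBX2 and TBX2-AS1; for each knockdown the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 2, no overlap between libraries and a symbol that is not a clone or pseudogene name; up to 4 called members with the smallest adjusted p in each gene list; the 5 largest differences each way between the knockdowns; the 4 genes each way with the largest smaller change in both knockdowns; and the neighbours of TBX2. Values of genes named by this rule are also given in the direct comparison. The values of some genes that the rule names are not reported here. The rule, the comparisons, the 26 gene lists and the alternatives were fixed before the data were examined, except where an alternative or test is said to be chosen later.

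The lists covered G1/S and replication, mitosis, p53 targets, adrenergic transcription factors, noradrenergic and neuronal genes, mesenchymal genes, matrix and adhesion, interferon, cholesterol, the integrated stress response, endoplasmic reticulum chaperones, hypoxia and glycolysis, ribosome biogenesis, apoptosis, immediate early genes, BMP, TGF-beta and WNT targets, TBX2 neighbours, T-box genes, RNA interference genes, ribosomal proteins, replication histones, and markers of Schwann and melanocyte lineage, fibroblasts and endothelium, leukocytes and epithelium. A list of transcripts encoded by mitochondrial DNA was not analysed here, because none of its 15 members matched. The symbols UHRF1, DACH1, NEFL, BOP1, PECAM1 and 6 histone genes did not match either. Lists with at least 5 tested members, 24 of them, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 in the 3 comparisons, and the 72 p values were adjusted together. All 23 calls were lost when the correlation was estimated, the lowest adjusted p being 0.46. Called members are counted over all genes and adjusted over the list alone. Beside camera, fry tested whether a list's genes move on balance one way.

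Sequences of 7 bases were counted in 3′ UTRs of at least 50 bases, from GENCODE release 29, for 13026 genes, and their enrichment in called genes was compared with 100 permutations of the genes within classes of UTR length. Shared controls were simulated 20 times without any change, from the fitted dispersions. In Python 3.11.15, tables were made with numpy 2.4.6 and pandas 2.3.3 and figures with matplotlib 3.10.9.

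Alternatives were DESeq2 size factors, upper-quartile scaling, no filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the 2 groups compared, replicate number as a block, leaving out each library, stricter thresholds (adjusted p under 0.01, or at least 2-fold), FPKM with pseudocounts of 0.1 and 1, with a mean FPKM of at least 0.5 or without a filter, and for lists fry and an estimated correlation. Simulated data had 200 changed genes. In a simulated siTBX2 comparison edgeR found 6%, 40% and 86% of the genes changed by 0.5, 1 and 3 on the log2 scale, with 6% of its calls false. In a simulated siTBX2-AS1 comparison it found 4%, 36% and 88%, with 9.9% of its calls false. DESeq2 had 32.1% and 38.6% false calls in these comparisons. Most simulated changes of 0.5 were missed by edgeR, so a gene that was not called may still have changed.

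Counts of genes that overlap on opposite strands or have pseudogenes are less certain, because strand use and the handling of shared reads were not stated. Of 117 named genes, 40 share at least 50 bp of exon with a gene on the other strand. They include MYCN (MYCNOS), ADD3, MCFD2, TANK, ITGA1, ITGAV, SHMT2, SLC7A5, RRP12, HSPE1 (HSPD1), KIF20A and GINS3, and RRM1, ANLN, MIAT, TMEM198 (CHPF), APC2, MOCS2, ACAT2, HMGCS1, STARD4, PDIA3, PPAT, XPO5 (POLR1C), DICER1, GARS1, CARS1, BMF, FNDC3A and DEPDC1. Pseudogenes named after them exist for 16, among them NPM1 with 45, HSPE1 with 26, GXYLT1 with 6, TOMM20 with 4 and SLC2A3 with 3.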

Results

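RNA was sequenced from NLF cells, a human neuroblastoma line grown from a tumour of the sympathetic lineage of the neural crest. The cells had received a small interfering RNA (siRNA) for 48 hours. One group received an siRNA against TBX2 (siTBX2), another an siRNA against the long noncoding RNA TBX2-AS1 (siTBX2-AS1), and the control group a non-targeting siRNA (siNTC). Each of the 3 groups had 3 biological replicates, 9 libraries in all. Total counts of replicates 1, 2 and 3 were 50490867, 42912762 and 43880732 in siNTC, 48457890, 42178655 and 46825008 in siTBX2, and 51434090, 38759410 and 31894280 in siTBX2-AS1. Between 25097 and 26680 genes had at least 1 count in a library, and 18367 genes were tested. Levels are means of 3 libraries in CPM (counts scaled to a common library total) ± SD, fold changes are on the log2 scale with their standard error (SE), and n = 3 in every group.

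The design asked what TBX2 and TBX2-AS1 do in neuroblastoma cells, so both target RNAs were read first in every group. TBX2 encodes a T-box transcription factor, mostly a repressor. It is gene ENSG00000121068.9 of the files, on the plus strand of chromosome 17 at 61399896 to 61409466 (GRCh38, GENCODE release 29). TBX2-AS1, gene ENSG00000267280.1, is an antisense RNA on the minus strand from 61393456 to 61411555, and its span contains all of TBX2. The exons of TBX2 and TBX2-AS1 share no stretch of 50 bp or more in that annotation. BCAS3 ends upstream at 61392838, and the noncoding gene LINC02875 lies downstream from 61411751 to 61413280, both on the plus strand.

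**Figure D1:**
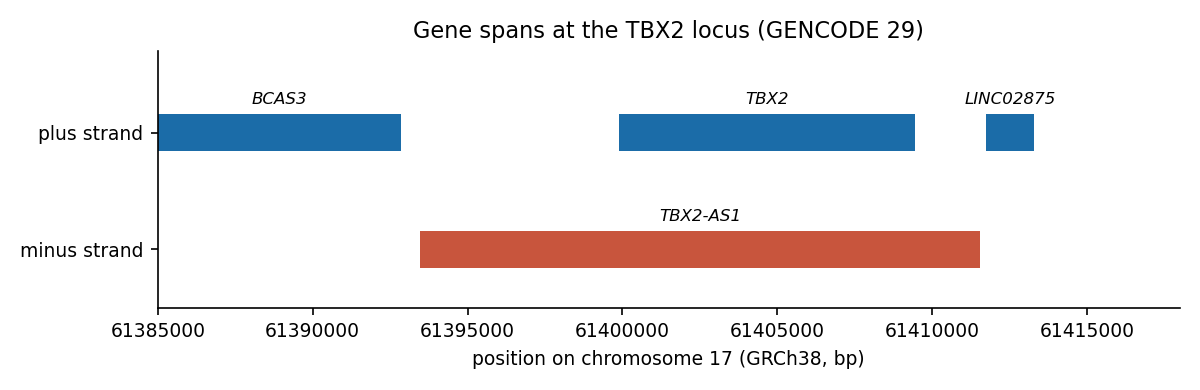
Gene spans around TBX2 on chromosome 17 (GRCh38 position on the horizontal axis), drawn from GENCODE release 29, with genes of the plus and minus strand in separate lanes. TBX2 lies inside the span of TBX2-AS1, which runs on the other strand.

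TBX2 fell in siTBX2 to 44.9% of its level in siNTC, from 260 ± 14.1 to 117 ± 9.31 CPM (log2 fold change -1.15, SE 0.11, adjusted p = 0.00734). TBX2-AS1 stayed at 35.6 ± 3.59 CPM in siTBX2 against 36.3 ± 2.01 in siNTC (log2 fold change -0.03, SE 0.52, adjusted p = 0.989). In siTBX2-AS1, TBX2-AS1 fell to 10.4% of its control level, 3.77 ± 2.71 CPM (log2 fold change -3.25, SE 0.57, adjusted p = 0.0184). The counts behind this were 244, 232 and 23 in the siTBX2-AS1 libraries, against 1912, 1465 and 1654 in siNTC. TBX2 was at 209 ± 30.5 CPM in siTBX2-AS1, 80.3% of the control level. It was not called over all tested genes (log2 fold change -0.32, SE 0.11, adjusted p = 0.172, unadjusted p = 0.0213 in the quasi-likelihood F test). The single-library values of TBX2 were 173.5, 228 and 224.3 CPM in siTBX2-AS1 and 275.9, 254.3 and 249.4 CPM in siNTC, without overlap. TBX2 was higher in siTBX2-AS1 than in siTBX2 (log2 fold change 0.84, SE 0.11, adjusted p = 0.00484). The exact two-sided permutation test on CPM gave p = 0.1, the smallest that 3 against 3 libraries allow, for TBX2 in each comparison and for TBX2-AS1 in siTBX2-AS1, and p = 0.8 for TBX2-AS1 in siTBX2. The authors' FPKM values gave 17.2 ± 1.38 against 39.8 ± 6.22 for TBX2 in siTBX2, and 1.09 ± 0.475 against 16.2 ± 0.889 for TBX2-AS1 in siTBX2-AS1. The call of TBX2-AS1 in siTBX2-AS1 ended without siNTC replicate 1 (log2 fold change -3.23, adjusted p = 0.0531), without siNTC replicate 3 (-3.25, 0.0505), without siTBX2-AS1 replicate 1 (-3.46, 0.0651), without a filter on low counts (-3.25, 0.058) and with only the 2 groups compared in the fit (-3.27, 0.0668). Whether reads were assigned by strand was not stated, which leaves the counts of the 2 genes less certain, although their exons share no stretch of 50 bp or more and TBX2-AS1 stayed level in siTBX2 where TBX2 fell.

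**Figure D2:**
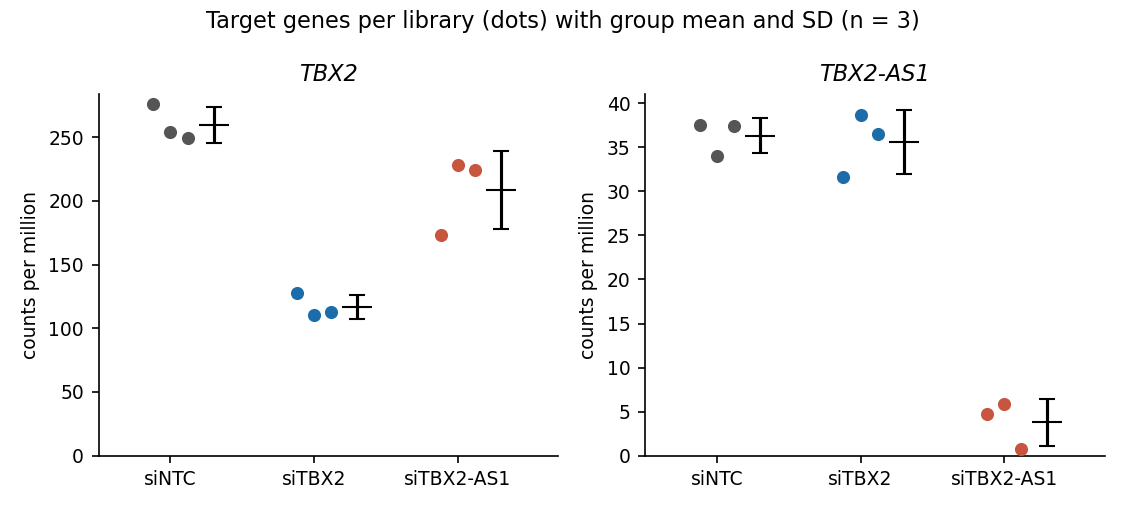
CPM of TBX2 and TBX2-AS1 (vertical axes, from 0) in siNTC, siTBX2 and siTBX2-AS1; each dot is 1 library, and bars with whiskers give the mean and SD (n = 3). TBX2 lay between 110.1 and 127.4 CPM in siTBX2 and between 173.5 and 228 CPM in siTBX2-AS1, and TBX2-AS1 lay between 0.714 and 5.872 CPM in siTBX2-AS1.

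Among 17 tested genes around TBX2 on chromosome 17, TBX2 alone was called in siTBX2, and it was also the only one adjusted over the list alone. The other 16 lay between -0.31 (APPBP2, adjusted p = 0.6) and 0.39 (TUBD1, adjusted p = 0.246) in log2 fold change. In siTBX2-AS1, TBX2-AS1 and RPS6KB1, the gene of a kinase of ribosomal protein S6, fell (RPS6KB1 log2 fold change -0.41, SE 0.07, adjusted p = 0.019), and 3 neighbours fell when adjusted over the list alone. LINC02875 stood at -0.81 (SE 0.46, adjusted p = 0.42) from a control level of 0.357 CPM, and MED13, a subunit of the Mediator kinase module, at -0.31 (SE 0.08, adjusted p = 0.0721). The neighbours as a set were not called in siTBX2 (camera adjusted p = 0.449) or siTBX2-AS1 (0.126), and fry, a rotation test, called them lower in siTBX2-AS1 (adjusted p = 0.028; 0.12 in siTBX2). TBX2 and TBX2-AS1 are themselves 2 of the 17. The 7-mer TTAAACT, found below in most searched genes that fell in siTBX2-AS1, was in the 3′ UTRs of 7 of 15 searched neighbours, RPS6KB1 and MED13 included. In a test chosen after seeing the data, the 8 without it had a median of 0.06 in siTBX2-AS1 and were not called (camera adjusted p = 0.844).

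The comparison of siTBX2 with siNTC asked which genes change when TBX2 is lowered. FBXO32, which encodes the ubiquitin ligase subunit atrogin-1, rose from 11.2 ± 3.12 to 37 ± 1.68 CPM (log2 fold change 1.72, SE 0.19, adjusted p = 0.00849, n = 3). MAOB, the gene of the amine-degrading enzyme monoamine oxidase B, rose from 14.5 ± 0.633 to 42.6 ± 9.02 CPM (1.55, SE 0.16, adjusted p = 0.00742). XPR1, which encodes a phosphate exporter, fell from 180 ± 23.2 to 77.8 ± 11.5 CPM (-1.21, SE 0.14, adjusted p = 0.00849), and ADD3, which encodes an adducin that caps and links the spectrin-actin cytoskeleton, fell from 77.1 ± 7.31 to 26.9 ± 4.86 CPM (-1.52, SE 0.17, adjusted p = 0.00923). POSTN, the gene of the matrix protein periostin, fell from 144 ± 55.9 to 38.5 ± 11.3 CPM (-1.90, SE 0.35, adjusted p = 0.0443). MYCN, the oncogenic transcription factor gene of neuroblastoma, which the antisense gene MYCNOS overlaps, rose from 263 ± 26.9 to 433 ± 15.2 CPM (0.72, SE 0.08, adjusted p = 0.00849).

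Of the 18367 genes tested, 146 rose and 149 fell in siTBX2. At least 2-fold changes were found for 19 that rose and 46 that fell. Other large rises were in NHSL2 (log2 fold change 1.93, SE 0.38), FBXO28 (1.34, SE 0.24), RAB33A, which encodes a Rab GTPase (1.31, SE 0.21), MCFD2, which encodes a cargo receptor subunit for coagulation factors (1.22, SE 0.13), LZTFL1, a regulator of ciliary protein trafficking (1.21, SE 0.13), and SH3BP5L (1.11, SE 0.22). Large falls were also seen in VWDE (-1.53, SE 0.13), NUDT16L1 (-1.49, SE 0.21), TNFAIP6, which encodes a hyaluronan-binding protein (-1.41, SE 0.24), SEMA3D, which encodes a secreted axon guidance protein (-1.27, SE 0.20), and TANK, which encodes a TRAF-binding adaptor (-1.21, SE 0.18). All 295 called genes had siTBX2 and siNTC libraries that did not overlap, as did 22.8% of all tested genes, against 10% given by chance. At an unadjusted p under 0.05 there were 2945 genes, where 918 are given by chance.

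Genes of ribosome biogenesis and nucleotide synthesis that MYC proteins activate were higher in siTBX2: 8 of 33 rose and none fell (14 rose adjusted over the list alone), and 31 had positive fold changes (median 0.23). RRP12 (0.51, SE 0.07) and UTP20 (0.54, SE 0.08), ribosome assembly factors, HSPE1, a mitochondrial chaperonin (0.40, SE 0.06), and NPM1, the nucleolar protein nucleophosmin (0.29, SE 0.05), were among them. The set was called (camera adjusted p = 3.49e-09; adjusted p = 0.46 with an estimated correlation). The ribosomal protein genes, read as a sign of library composition, moved with it: 35 of 36 had positive fold changes (median 0.15), and the set was called (camera adjusted p = 8.07e-09; adjusted p = 0.46 with an estimated correlation). No ribosomal protein gene was called by edgeR on its own or by limma-voom, 3 were by DESeq2, 16 had an unadjusted p under 0.05, and 6 rose adjusted over the list alone.

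Integrated stress response genes were higher as a set (28 tested, median 0.19, camera adjusted p = 0.000355; adjusted p = 0.46 with an estimated correlation). SHMT2, a serine hydroxymethyltransferase gene (0.48, SE 0.08), and SLC7A5, an amino acid transporter gene (0.80, SE 0.13), rose, and 7 rose adjusted over the list alone. Mitotic genes were also higher (30 of 37 positive, median 0.12, camera adjusted p = 0.00071; adjusted p = 0.57 with an estimated correlation). The cyclin B1 gene CCNB1 (0.34, SE 0.06) and the mitotic kinesin gene KIF20A (0.28, SE 0.06) rose, and no others were added adjusted over the list alone. G1/S and replication genes were lower (11 of 39 positive, median -0.12, camera adjusted p = 0.00342; adjusted p = 0.48 with an estimated correlation). In that list CDC45, which encodes a subunit of the replicative helicase, fell (-0.46, SE 0.09) and GINS3, which encodes another, rose (0.39, SE 0.06), with 3 up and 5 down adjusted over the list alone. Cholesterol genes were higher (24 tested, median 0.12, camera adjusted p = 0.0295; adjusted p = 0.70 with an estimated correlation), and 2 members rose adjusted over the list alone. The cholesterol call held in 5 of the 9 fits without 1 library and ended with only the 2 groups compared (adjusted p = 0.0567), and the mitotic call held in 8 of the 9.

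Interferon-stimulated genes were lower as a set in siTBX2 (5 of 31 positive, median -0.26, camera adjusted p = 0.000958; adjusted p = 0.49 with an estimated correlation). No member was called by edgeR or limma-voom or adjusted over the list alone, 1 fell by DESeq2, and 8 were lower at an unadjusted p under 0.05. Immediate early genes were higher (20 of 25 positive, median 0.38, camera adjusted p = 0.00651; adjusted p = 0.46 with an estimated correlation). No immediate early gene was called by edgeR or limma-voom, 1 rose by DESeq2, 5 were higher at an unadjusted p under 0.05, and 1 rose adjusted over the list alone. The immediate early call ended in 1 of the 9 fits without 1 library (adjusted p = 0.0642) and with FPKM (0.0537 and 0.0538).

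Neuronal genes split in siTBX2. GAP43, an axon growth gene, fell from 133 ± 16.1 to 69.3 ± 3.74 CPM (-0.94, SE 0.11, adjusted p = 0.00878), as did the synaptic vesicle genes SNAP25 (-0.83, SE 0.13) and SYT4 (-0.98, SE 0.16), while the secretogranin gene SCG2 rose (0.57, SE 0.10). The noradrenergic and neuronal list of 31 genes was not called (adjusted p = 0.667; 5 rose and 6 fell adjusted over the list alone), and its median of 0.03 and mean of 0.04 had the other sign than its test. Among 21 adrenergic transcription factor genes, MYCN rose, with 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.767). Of 29 matrix and adhesion genes 3 fell, POSTN, the integrin alpha-1 gene ITGA1 (-1.13, SE 0.11) and the lumican gene LUM (-0.59, SE 0.10), and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.08). The 30 mesenchymal genes held no call by edgeR or limma-voom, with 1 up and 1 down by DESeq2 and 4 up and 2 down at an unadjusted p under 0.05 (camera adjusted p = 0.95).

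Single members of other lists changed in siTBX2: PDIA4 rose in the endoplasmic reticulum chaperone list (0.47, SE 0.09; 21 tested, camera adjusted p = 0.802), HK2 (0.58, SE 0.07) and KDM3A (0.51, SE 0.10) in the hypoxia and glycolysis list (24 tested, 0.71), and ID4 in the BMP, TGF-beta and WNT list (0.50, SE 0.08; 23 tested, 0.0882). The apoptosis list was not called (25 tested, 0.667). Adjusted over the list alone, 3 rose and 2 fell in the chaperone list, 2 rose and 1 fell in the hypoxia list, 2 rose in the BMP list, and 2 rose and 1 fell in the apoptosis list. The p53 target list (30 tested, camera adjusted p = 0.449), other T-box genes (5 tested, 0.804), RNA interference genes (12 tested, 0.8) and replication histones (15 tested, 0.989) held no edgeR call. At an unadjusted p under 0.05, 4 p53 targets, 2 RNA interference genes and 1 histone gene were higher, and DESeq2 called 1 p53 target and 2 RNA interference genes. Adjusted over the list alone, 2 RNA interference genes rose and no member of the other 3 lists changed. For the T-box and histone lists the signs of median, mean and test differed.

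The 3′ UTRs of 134 of the 149 genes that fell could be searched, and 47.0% contained the 7-mer CAGAATG, against 25.1% in permutations among genes of similar 3′ UTR length, 16.7% of genes called in neither knockdown and 15.4% of those that rose. POSTN, ADD3, SEMA3D, XPR1 and CDC45 carried it, and VWDE, NUDT16L1, TNFAIP6, TANK, GAP43, SNAP25, SYT4, ITGA1 and LUM did not. Of 136 searched genes that rose, 19 contained AGACGTA, against 1.8% in permutations and 1.6% of genes called in neither knockdown. FBXO32, MCFD2, LZTFL1, GINS3 and TOMM20 carried it, and MAOB, NHSL2, FBXO28, RAB33A, SH3BP5L and MYCN did not. The count of 295 genes dropped without any single library, to 44, 91 and 51 without siTBX2 replicates 1, 2 and 3, to 52, 135 and 74 without siNTC replicates 1, 2 and 3, and to 177, 136 and 174 without siTBX2-AS1 replicates 1, 2 and 3, which enter the estimate of the spread. With replicate number as a block it was 873. POSTN (adjusted p from 0.0572 to 0.127), CCNB1, KIF20A (0.0893 to 0.194), CDC45, GINS3, ID4, KDM3A, NPM1 and PDIA4 were called in none of the 9 fits without 1 library, and FBXO32, MAOB, XPR1, ADD3, VWDE, MYCN and GAP43 in all 9.

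**Figure D3:**
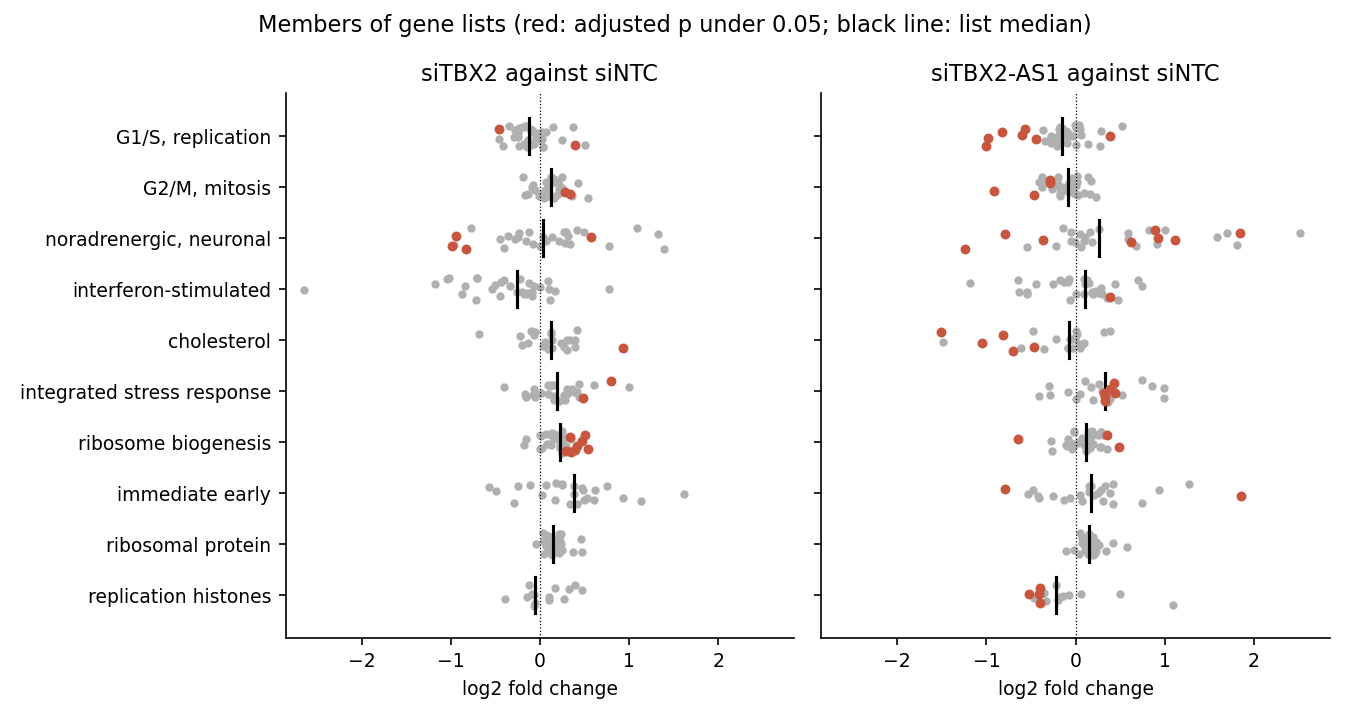
Log2 fold change (horizontal axis) of each tested member of 10 gene lists in siTBX2 and in siTBX2-AS1 against siNTC; each dot is a gene, red dots passed an adjusted p of 0.05, and the black line is the list's median. The mitotic genes had a median of 0.12 in siTBX2 and -0.09 in siTBX2-AS1.

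The comparison of siTBX2-AS1 with siNTC asked which genes change when the antisense RNA is lowered. MAP6, which encodes a microtubule-stabilising protein of neurons, rose from 1.89 ± 0.165 to 10.3 ± 2.59 CPM (log2 fold change 2.44, SE 0.25, adjusted p = 0.00162, n = 3), and INA, the gene of the neurofilament protein alpha-internexin, from 7.62 ± 0.252 to 27.2 ± 3.15 CPM (1.84, SE 0.12, adjusted p = 0.000315). SGPP1, which encodes a sphingosine-1-phosphate phosphatase, fell from 20.8 ± 1.46 to 4.94 ± 0.766 CPM (-2.07, SE 0.13, adjusted p = 0.000315), and SLC39A10, a zinc importer gene, from 188 ± 15 to 47.9 ± 13 CPM (-1.97, SE 0.19, adjusted p = 0.00138). CDK1, the gene of the main mitotic kinase, fell from 183 ± 15.9 to 97.7 ± 7.42 CPM (-0.91, SE 0.09, adjusted p = 0.00114). SGPP1, SLC39A10 and CDK1 each carried the 7-mer TTAAACT in the 3′ UTR.

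In siTBX2-AS1, 329 genes rose and 511 fell, 62 and 112 of them at least 2-fold. Besides MAP6 and INA, the largest rises were in the zinc finger gene ZNF813 (2.36, SE 0.16), TMEM198 (2.14, SE 0.24), TMEM196 (2.01, SE 0.45), the long noncoding RNA MIAT (1.92, SE 0.29), APC2, a neuronal relative of APC (1.76, SE 0.22), and AP3B2, a subunit gene of the neuronal AP-3 complex (1.59, SE 0.20). Large falls were in ITGA2, which encodes a collagen-binding integrin subunit (-1.90, SE 0.41), MOCS2, a molybdopterin synthase gene (-1.87, SE 0.16), HCCS, which encodes the enzyme that attaches haem to cytochrome c (-1.82, SE 0.12), the Y RNA gene RNY1 (-1.82, SE 0.33), and GXYLT1, a xylosyltransferase gene (-1.75, SE 0.12). Every called gene had siTBX2-AS1 and siNTC libraries that did not overlap, as did 24% of tested genes against 10% given by chance, and 3377 genes had an unadjusted p under 0.05.

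Cell cycle genes were lower in siTBX2-AS1. Of 39 G1/S and replication genes 6 fell and 1 rose (2 rose and 10 fell adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.000429; adjusted p = 0.46 with an estimated correlation). Those that fell included the histone stem-loop binding protein gene SLBP (-0.83, SE 0.14), the chromatin assembly factor gene CHAF1B (-0.60, SE 0.08) and the ribonucleotide reductase gene RRM1 (-0.57, SE 0.06). Of 37 mitotic genes 4 fell and 6 fell adjusted over the list alone, CDK1, the cytokinesis gene ANLN (-0.47, SE 0.10), CCNB1 (-0.29, SE 0.06) and DLGAP5 (-0.29, SE 0.07) among them (camera adjusted p = 0.00161; adjusted p = 0.58 with an estimated correlation). Replication-dependent histone genes, a list chosen as a sign of RNA or library quality, were also lower. Of 15 tested, H1-5 (-0.52, SE 0.08), H2BC4 (-0.40, SE 0.08), H1-2 (-0.40, SE 0.09) and H1-4 (-0.41, SE 0.09) fell, with 1 up and 6 down adjusted over the list alone. The list was called (camera adjusted p = 0.00134, and adjusted p = 0.46 with an estimated correlation). Whether these falls reflect the cell cycle or library quality was not tested. TTAAACT was present in SLBP, CHAF1B, RRM1 and CDK1 and absent from ANLN, CCNB1, DLGAP5, H2BC4 and H1-4.

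Of 24 cholesterol genes 5 fell and none rose by edgeR, and 2 rose and 9 fell adjusted over the list alone. ACAT2, which makes acetoacetyl-CoA (-1.51, SE 0.14), HMGCS1, which makes the precursor of mevalonate (-0.82, SE 0.10), DHCR7, which makes cholesterol from its last precursor (-1.05, SE 0.20), and STARD4, a sterol carrier (-0.70, SE 0.10), were 4 of them. The list was called (median -0.07, camera adjusted p = 0.00342; adjusted p = 0.58 with an estimated correlation), all 5 fallen members carried TTAAACT, and among members without it the list was not called (adjusted p = 0.538).

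Noradrenergic and neuronal genes were higher as a set (31 tested, median 0.26, camera adjusted p = 0.0118; adjusted p = 0.46 with an estimated correlation). INA, SYT4 (0.92, SE 0.16) and SCG2 (0.62, SE 0.10) were 3 of 5 that rose, and ELAVL4, which encodes a neuronal RNA-binding protein, was 1 of 3 that fell (-1.24, SE 0.12), with 6 up and 4 down adjusted over the list alone. The call ended with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.122), with FPKM (0.241 and 0.239), with fry (0.0532) and in 1 of the 9 fits without 1 library (0.0618). Integrated stress response genes were higher: 6 of 28 rose, among them the tRNA synthetase genes AARS1 (0.44, SE 0.08), GARS1 (0.43, SE 0.09) and CARS1 (0.39, SE 0.08) and the serine synthesis gene PHGDH (0.32, SE 0.06), with 11 up and 1 down adjusted over the list alone (camera adjusted p = 1.33e-05; adjusted p = 0.46 with an estimated correlation). Ribosome biogenesis genes had a median of 0.12 (33 tested, camera adjusted p = 0.0377; adjusted p = 0.57 with an estimated correlation). RRP12 (0.49, SE 0.07) and the rRNA methyltransferase gene FBL (0.35, SE 0.08) rose and the purine synthesis gene PPAT fell (-0.65, SE 0.13), with 4 up and 2 down adjusted over the list alone, and the list's call held in 4 of the 9 fits without 1 library and ended with DESeq2 (adjusted p = 0.102), with at least 1 CPM in 3 libraries (0.1), with only the 2 groups compared (0.0526) and with FPKM (0.0681 to 0.194). Ribosomal protein genes were higher here too, 34 of 36 positive with a median of 0.16 (camera adjusted p = 1.09e-07; adjusted p = 0.46 with an estimated correlation). None was called by edgeR or limma-voom, 2 were by DESeq2, 16 had an unadjusted p under 0.05, and 4 rose adjusted over the list alone. siTBX2 was compared with the same siNTC libraries. In siTBX2-AS1 against siTBX2, 18 of 36 were positive (median 0, camera adjusted p = 0.95).

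Lists not called in siTBX2-AS1 still held changed genes. All fallen genes named in this paragraph carried TTAAACT in the 3′ UTR, ITGA1, ITGAV, SNAI2 and PDIA3 included. DICER1 (-0.61, SE 0.14), the precursor exporter gene XPO5 (-0.30, SE 0.06) and the Argonaute partner gene TNRC6B (-0.70, SE 0.10) fell among 12 RNA interference genes, all with TTAAACT (1 up and 5 down adjusted over the list alone; camera adjusted p = 0.301). MYCN rose from 263 ± 26.9 to 346 ± 2.35 CPM (0.39, SE 0.08, adjusted p = 0.0258), the only call of 21 adrenergic factor genes and the only one adjusted over the list alone (camera adjusted p = 0.994). ITGA1 (-0.97, SE 0.11) and the integrin alpha-V gene ITGAV (-0.44, SE 0.06) fell and the collagen gene COL1A1 rose (0.66, SE 0.14) among 29 matrix genes (1 up and 3 down adjusted over the list alone; 0.844), whose median of 0.12 had the other sign than the test. TGFBR2 rose (0.61, SE 0.11) and SNAI2 fell (-0.90, SE 0.19) among 30 mesenchymal genes, with no more adjusted over the list alone (0.802). The glucose transporter gene SLC2A3 rose (1.55, SE 0.26) among 24 hypoxia genes, alone also when adjusted over the list alone (0.147). The 31 interferon genes were not called as a set (2 rose adjusted over the list alone; 0.848). PDIA4 rose (0.48, SE 0.09) and PDIA3 fell (-0.42, SE 0.09) among 21 chaperone genes, the same number adjusted over the list alone (0.502). BMF rose (0.88, SE 0.16) among 25 apoptosis genes (2 up and 1 down adjusted over the list alone; 0.989).

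NR4A3 rose from 0.294 to 1.08 CPM (1.85, SE 0.37) and the RAS-MAPK inhibitor gene SPRED1 fell (-0.79, SE 0.10) among 25 immediate early genes in siTBX2-AS1, as many as adjusted over the list alone (camera adjusted p = 0.481). SKIL (-0.51, SE 0.12) and ID1 (-0.44, SE 0.10) fell among 23 BMP, TGF-beta and WNT target genes, as many as adjusted over the list alone (0.651). SPRED1 and SKIL carried TTAAACT, and ID1 did not. The p53 list (30 tested, 0.926) held no call by edgeR, DESeq2 or limma-voom and none at an unadjusted p under 0.05, and other T-box genes (5 tested, 0.926) held 1 at an unadjusted p under 0.05 and none by the 3 tools. The signs of median, mean and test differed for the p53, adrenergic and T-box lists.

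In siTBX2-AS1, 463 of the 511 fallen genes had a 3′ UTR to search, and 65.9% of these contained TTAAACT, against 26.3% in permutations among genes of similar 3′ UTR length, 18.7% of genes called in neither knockdown and 10.2% of those that rose. ITGA2, MOCS2, HCCS, GXYLT1 and ELAVL4 also carried it. Over all 2644 genes with the 7-mer the median log2 fold change was -0.12, against 0.05 for genes without it. Without the carriers and the genes that could not be searched, a count chosen after seeing the data, 423 calls were left, 265 up and 158 down. The count of 840 fell to 402, 505 and 449 without siTBX2-AS1 replicates 1, 2 and 3 and to 481, 467 and 511 without siNTC replicates 1, 2 and 3; ITGA2, TMEM196 and CCNB1 were each called in 2 of the 9 fits without 1 library and DLGAP5 in none (adjusted p from 0.0612 to 0.143).

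**Figure D4:**
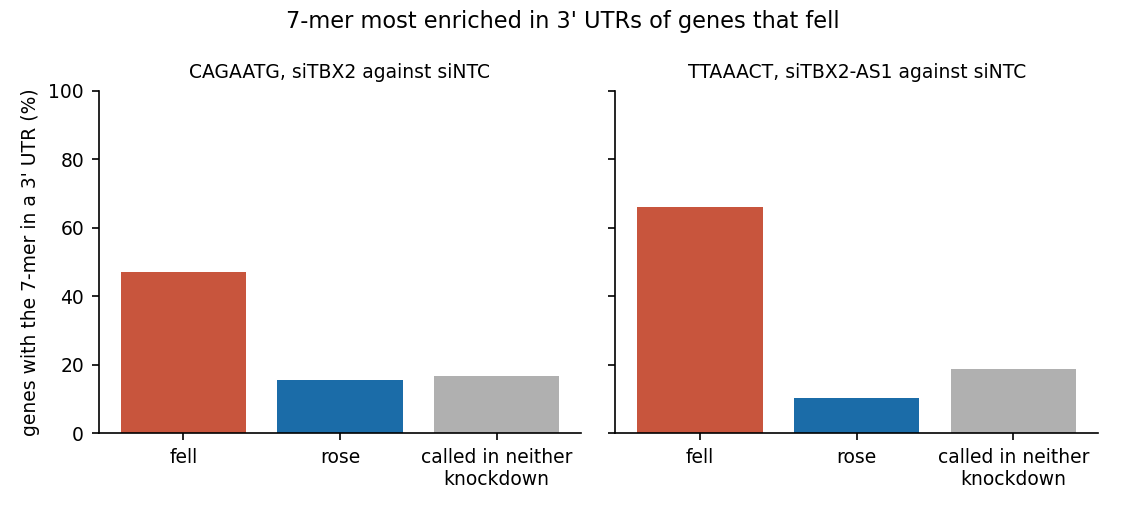
Percent of searched genes (vertical axis, from 0) whose 3′ UTR contains CAGAATG or TTAAACT, for genes that fell, rose or were called in neither knockdown. TTAAACT was found in 65.9% of the genes that fell in siTBX2-AS1 and CAGAATG in 47.0% of those that fell in siTBX2.

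The direct comparison of siTBX2-AS1 with siTBX2 tested where the effects of the 2 knockdowns differ, with the control libraries entering only the estimate of the spread. SYT4, a synaptotagmin gene, was higher in siTBX2-AS1 (38.1 ± 2.67 CPM) than in siTBX2 (10.3 ± 1.9 CPM; log2 difference 1.89, SE 0.16, adjusted p = 0.000709, n = 3). SERPINE2, the gene of a secreted protease inhibitor, was lower in siTBX2-AS1 (4.65 ± 0.354 CPM) than in siTBX2 (26.6 ± 6.13 CPM; -2.52, SE 0.18, adjusted p = 0.000434). DEPDC1, a gene expressed in dividing cells, was lower as well (28.8 ± 1.12 against 121 ± 26.4 CPM; -2.07, SE 0.17, adjusted p = 0.000584). MAP6 (2.66, SE 0.25), VWDE (2.13, SE 0.14), ZNF813 (2.11, SE 0.16) and TNFAIP6 (1.90, SE 0.24) were higher in siTBX2-AS1, and JAGN1 (-2.74, SE 0.65) and NHSL2 (-2.25, SE 0.39) were lower. SERPINE2, DEPDC1 and NHSL2 carried TTAAACT in the 3′ UTR, and JAGN1 did not.

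In all, 373 genes were higher and 642 lower in siTBX2-AS1 than in siTBX2, 89 and 142 of them at least 2-fold. TTAAACT was in 57.7% of the 589 searched genes that were lower, against 24.5% in permutations, and CAGAATG in 34.4% of the 340 searched genes that were higher, against 21.1%. Mitotic genes were lower in siTBX2-AS1: none of the 37 had a positive difference (median -0.23), 8 were called lower and 12 adjusted over the list alone, CDK1 (-1.05), CCNB1 (-0.62) and KIF20A (-0.27) included (camera adjusted p = 3.49e-09; adjusted p = 0.46 with an estimated correlation). Cholesterol genes were lower in siTBX2-AS1, 6 of 24 called and 9 adjusted over the list alone (ACAT2 -1.41 and HMGCS1 -0.94, both with TTAAACT; camera adjusted p = 2.19e-07; adjusted p = 0.46 with an estimated correlation). Replication histones (3 of 15 lower, 8 adjusted over the list alone; camera adjusted p = 0.00134) and ribosome biogenesis genes (5 of 33 lower, 6 adjusted over the list alone, UTP20 -0.64 and HSPE1 -0.51 among them; 0.00416) were lower too (adjusted p = 0.46 with an estimated correlation for either). BMP, TGF-beta and WNT target genes were lower (1 of 23 called, 1 up and 4 down adjusted over the list alone; camera adjusted p = 0.0111; adjusted p = 0.46 with an estimated correlation), a call that ended in 1 of the 9 fits without 1 library (adjusted p = 0.0651). Neuronal genes were higher in siTBX2-AS1, 7 of 31 called higher and 1 lower (8 and 1 adjusted over the list alone), with SNAP25 at 0.94, GAP43 at 0.72, INA at 1.42 and ELAVL4 at -1.12 (camera adjusted p = 0.00409; adjusted p = 0.46 with an estimated correlation). Interferon genes were higher, 2 of 31 called and 4 adjusted over the list alone (median 0.30, camera adjusted p = 0.00159; adjusted p = 0.53 with an estimated correlation). MYCN was lower in siTBX2-AS1 than in siTBX2 (-0.32, adjusted p = 0.0485). The other lists tested had camera adjusted p values from 0.159 to 0.95, with signs of median, mean and test that differed for the mesenchymal, T-box, fibroblast, epithelial and ribosomal protein lists.

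The 1015 differences became 469, 554 and 553 without siTBX2 replicates 1, 2 and 3 and 491, 596 and 536 without siTBX2-AS1 replicates 1, 2 and 3. With replicate number as a block they were 2084. JAGN1 was called in 1 of the 9 fits without 1 library, and SYT4, SERPINE2, DEPDC1, MAP6, VWDE, ZNF813 and TNFAIP6 in all 9.

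Some genes changed the same way in both knockdowns. TOMM20, which encodes a receptor of the mitochondrial protein import channel, rose from 302 ± 43.5 CPM to 611 ± 49.8 in siTBX2 (log2 fold change 1.02, SE 0.11) and 577 ± 39.1 in siTBX2-AS1 (0.93, SE 0.11; n = 3). LZTFL1 (1.21 and 1.12), RAB33A (1.31 and 1.04) and MAOB (1.55 and 0.99) rose in siTBX2 and siTBX2-AS1. ITGA1 (-1.13 and -0.97), TANK (-1.21 and -0.98), GPD2, which encodes mitochondrial glycerol-3-phosphate dehydrogenase (-0.99 and -0.92), and FNDC3A (-0.92 and -0.94) fell in both. Altogether 54 genes rose and 38 fell in both knockdowns and 8 moved in opposite directions, where independent lists would give 2.62, 4.15 and 6.73. The 7-mer AGACGTA was in 19.1% of the 47 searched genes that rose in both against 1.7% in permutations among genes of similar 3′ UTR length and 1.6% of genes called in neither. TOMM20 and LZTFL1 carried it, and RAB33A and MAOB did not. Of the genes named that fell in both, GPD2 carried CAGAATG and TTAAACT, FNDC3A CAGAATG, ITGA1 TTAAACT, and TANK neither. CAGAATG was in 62.5% of the 32 searched genes that fell in both (enrichment z = 5.15). It was in 16.7% of genes called in neither, which were not matched for UTR length. CAGAATG was picked among all genes that fell in siTBX2, and the 32 genes are part of these, so their share is no separate evidence. No 7-mer passed the permutations for these genes (highest enrichment z = 5.5, 95th percentile of permutations 8.75).

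Because both comparisons use the same 3 siNTC libraries, fold changes correlate even without shared effects. This holds for gene lists too. The ribosomal protein, stress response and G1/S lists were called the same way in both knockdowns. Between the knockdowns their medians were 0, 0.02 and -0.02 (camera adjusted p = 0.95, 0.545 and 0.376). For these lists a shift in siNTC cannot be told apart from a change shared by both knockdowns. In 20 simulations in which no gene changed and both comparisons used the same controls, no gene was called the same way in both, against 92 here. With no effect hardly any gene is called in either comparison, so the simulated value is chance with no effect and no measure of the overlap of real effects. Across 12049 genes, which are not independent replicates, the correlation of the fold changes was 0.46, against 0.51 in the simulations (0.47 to 0.57), and their covariance 0.062 against 0.04 (0.034 to 0.052). The variance of the siNTC mean was 0.045, and part of the excess over either value can come from the shared controls, since 3 controls cannot be split into sets of 2. The 92 genes became 24, 58 and 29 without siNTC replicates 1, 2 and 3, 19, 27 and 21 without siTBX2 replicates 1, 2 and 3, and 46, 45 and 47 without siTBX2-AS1 replicates 1, 2 and 3. With replicate number as a block they were 298. The simulations held no component shared by replicates of the same number, although such libraries correlated, as given below.

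**Figure D5:**
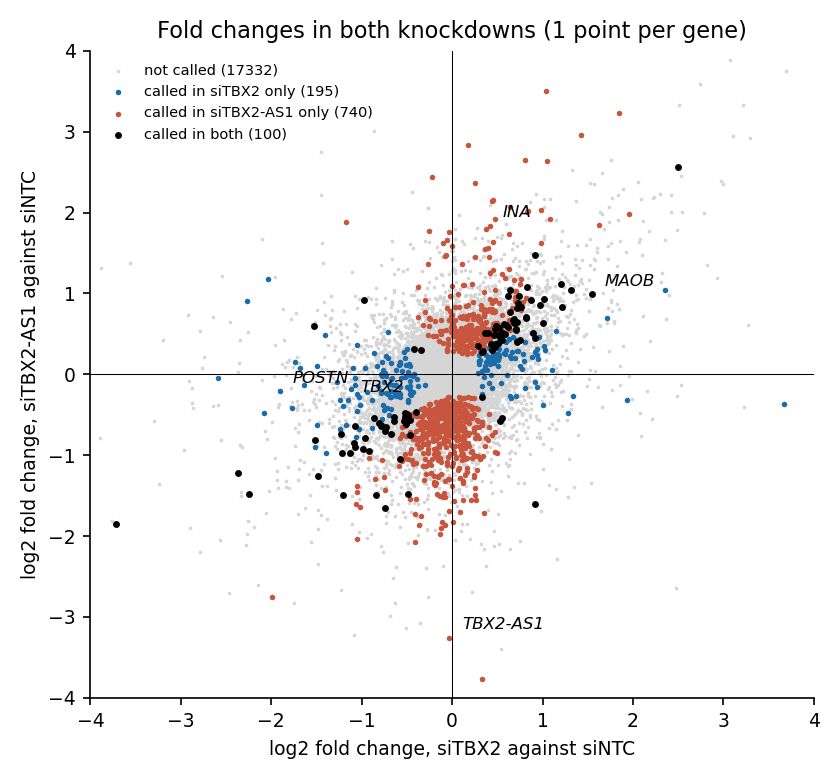
Log2 fold change against siNTC in siTBX2 (horizontal axis) and siTBX2-AS1 (vertical axis) of each tested gene, coloured by where it was called; 47 genes lie outside the axes. Of the genes, 195 were called in siTBX2 only, 740 in siTBX2-AS1 only and 100 in both.

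Leukocyte, epithelial and Schwann lineage markers were mostly low in siNTC, and several markers of the fibroblast and endothelial list were not. Of 16 leukocyte markers 15 were under 1 CPM, the highest being CD68 at 1.47, and of 14 epithelial markers 11 were, the highest being KRT18 at 5.51. Of 15 Schwann and melanocyte lineage markers 10 were under 1 CPM, the highest being the myelin gene PMP22 at 13.6. Of 16 fibroblast and endothelial markers 8 were under 1 CPM, but the collagen gene COL3A1, also on the matrix list, stood at 803 CPM in siNTC, 820 in siTBX2 and 873 in siTBX2-AS1. In siNTC, LUM stood at 127, PDGFRB at 62.6, THY1 at 41.9, DCN at 35.5 and PDGFRA at 23.1 CPM. Among tested markers LUM fell in siTBX2, and the melanocyte gene DCT rose in siTBX2-AS1 from 1.53 to 2.98 CPM (0.95, SE 0.17). Adjusted over the list alone, LUM and DCT were called, 1 Schwann lineage marker rose in siTBX2 and 1 epithelial marker fell in siTBX2-AS1. No marker list was called in siTBX2 (camera adjusted p = 0.989 for Schwann lineage, 0.481 for fibroblast and endothelial, 0.802 for epithelial) or siTBX2-AS1 (0.333, 0.168 and 0.8), and in siTBX2 the signs of median, mean and test differed for the Schwann and fibroblast lists. The 4 tested leukocyte markers were too few for camera, and none was called by edgeR, DESeq2 or limma-voom or had an unadjusted p under 0.05 in either knockdown.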

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

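The 7-mer alternative was chosen after seeing the data; all others were planned. TBX2 in siTBX2 and TBX2 in siTBX2-AS1 kept their direction and their side of the threshold in every setting run. TBX2-AS1 in siTBX2 was called in none, with values around 0 of either sign (-0.11 to 0.03). Counts of calls in siTBX2, in siTBX2-AS1, between the knockdowns, and the same way in both are given in that order. They were 287, 828, 1019 and 87 with DESeq2 size factors, 257, 828, 976 and 80 with upper-quartile scaling, 333, 943, 1126 and 99 with at least 1 CPM in 3 libraries, and 313, 815, 1056 and 87 with limma-voom. With DESeq2 they were 1053, 1618, 1966 and 312, and with FPKM 35, 368, 455 and 14 (pseudocount 0.1), 34, 376, 466 and 15 (pseudocount 1), and 17, 169, 227 and 9 (no filter); the cause was not tested. Without a filter on low counts, which tests more genes, they were 184, 629, 785 and 56, and with only the 2 groups compared, which has fewer samples, 52, 461, 740 and 18. TBX2-AS1 in siTBX2-AS1 was at -3.25 (adjusted p = 0.058) and -3.27 (0.0668) in these last settings, no longer called. Stricter thresholds gave 30, 260, 337 and 11 at an adjusted p under 0.01, and 65, 174 and 231 with at least 2-fold changes. Restricted to genes with a searched 3′ UTR lacking TTAAACT, which are fewer genes, siTBX2-AS1 had 423 calls. No called gene changed sign in a setting that used counts. With FPKM, 6 genes called in siTBX2-AS1 and 3 called between the knockdowns changed sign with either pseudocount, and 1 in siTBX2, 7 in siTBX2-AS1 and 3 between the knockdowns without a filter.

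Leaving out 1 library, with fewer samples, gave 44 to 177 calls in siTBX2, 402 to 654 in siTBX2-AS1, 469 to 918 between the knockdowns and 19 to 58 the same way in both. The lowest counts came without siTBX2 replicate 1 (44, 469 and 19) and without siTBX2-AS1 replicate 1 (402). TBX2-AS1 in siTBX2-AS1 ranged from -3.71 to -2.79 and was no longer called without siNTC replicate 1 (-3.23), siNTC replicate 3 (-3.25) or siTBX2-AS1 replicate 1 (-3.46). Of 43 named calls in siTBX2, 14 held in all 9 of these fits and 11 in none; of 69 in siTBX2-AS1, 30 and 1; of 9 between the knockdowns, 7 and 0. For the lists, 23 calls were lost with an estimated correlation and 13 with fry, which added 1, the TBX2 neighbours in siTBX2-AS1. Those lost with fry were the G1/S, mitotic, interferon, cholesterol, stress response and immediate-early lists in siTBX2, the mitotic, neuronal, cholesterol, ribosome biogenesis and histone lists in siTBX2-AS1, and the interferon and histone lists between the knockdowns. The immediate-early list in siTBX2 and the ribosome biogenesis list between the knockdowns were lost with FPKM too.

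Replicates of the same number had positively correlated deviations from their group means (0.07 to 0.24, against at most 0.02 for other pairs), and 7 of 9 such pairs passed 0.1. All 9 libraries correlated best with their own number. On the first principal component of log2 CPM (18.9% of the variance), replicates 1, 2 and 3 stood at -26.2, -7.8 and 38.3 in siNTC. They stood at -40, -16.2 and 23.2 in siTBX2 and at -19.5, -3.6 and 51.8 in siTBX2-AS1, the same order in each group. The labels do not pair the libraries, so the pairing rests on the data and not on a stated design. The main counts do not account for it. With replicate number as a block the counts were 873, 1741, 2084 and 298, with TBX2 at -1.15 in siTBX2 (adjusted p = 0.0153) and TBX2-AS1 at -3.40 in siTBX2-AS1 (0.0281).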

Other observations

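The search for a control siRNA seed in the genes that rose in both knockdowns, and the count of genes without TTAAACT, were chosen after the results were seen.

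A few genes moved in opposite directions in the knockdowns. SYT4 fell in siTBX2 (log2 fold change -0.98, SE 0.16) and rose in siTBX2-AS1 (0.92, SE 0.16; n = 3), and VWDE did likewise (-1.53, SE 0.13 and 0.60, SE 0.13). CCNB1 rose in siTBX2 (0.34, SE 0.06) and fell in siTBX2-AS1 (-0.29, SE 0.06), as did SERPINE2 (0.92, SE 0.17 and -1.60, SE 0.18). Without 1 library, CCNB1 was called in 0 of 9 fits in siTBX2 and 2 of 9 in siTBX2-AS1. The other 4 were chosen after their values were seen. UBE2G1, a ubiquitin-conjugating enzyme gene (0.55, SE 0.07 and -0.54, SE 0.07), and PNRC2, a nuclear receptor coactivator gene (0.53, SE 0.08 and -0.58, SE 0.08), rose in siTBX2 and fell in siTBX2-AS1. NRIP1, a nuclear receptor corepressor gene (-0.42, SE 0.07 and 0.32, SE 0.07), and PTPRK, a receptor phosphatase gene (-0.35, SE 0.07 and 0.30, SE 0.07), did the reverse. The difference between the knockdowns was called for all 8 (adjusted p from 0.000257 for UBE2G1 and VWDE to 0.00166 for PTPRK). These genes were picked for calls of opposite sign in the same fit, so that call was nearly given in advance and adds no evidence. Independent lists would give 6.73 such genes, close to the 8 found. SERPINE2, PNRC2 and UBE2G1 carried TTAAACT in the 3′ UTR, and NRIP1 and UBE2G1 carried CAGAATG.

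The genes that fell in siTBX2-AS1 may include unintended targets of the siRNA, silenced through matches to its seed as a microRNA would. TTAAACT had the highest enrichment of all 7-mers in their 3′ UTRs (z = 20.22), above each of 100 permutations (highest 6.61), and the genes that rose had z = -3.83. The 7-mer is present in TBX2-AS1 transcripts, which a seed match of this siRNA requires, and not in TBX2 transcripts. The siRNA sequence was not given in the sources used here, and the 158 fallen genes without the 7-mer leave an effect of lower TBX2-AS1 open, which was not tested. Without the carriers and the genes not searched, the camera calls of the G1/S (adjusted p = 0.000303), mitotic (0.000265), neuronal (0.00962), stress response (1.81e-05), ribosome biogenesis (0.0364) and ribosomal protein (5.46e-05) lists held at the preset correlation, and that of the cholesterol list (0.538) did not. With an estimated correlation none of these lists was called among all members (adjusted p from 0.46 to 0.58). The histone list was not called either (0.105), with 7 of 15 members left, but its median was -0.33 against -0.22 for all members and none of its 4 fallen genes was found with TTAAACT (2 were not searched). The p values without carriers were adjusted over the lists of this comparison alone, among genes without TTAAACT, unlike those for all members. The shifted 7-mer TAAACTA (z = 18.38) was in 49.7% of the searched fallen genes. Any genes with TAAACTA but not TTAAACT stayed in these tests, so the tests do not remove every possible seed match.

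For the genes that fell in siTBX2 the same explanation cannot be told apart from an effect of lower TBX2. CAGAATG had z = 7.25, above the 95th percentile of the permutations (6.59) but below their highest value (7.28), so the result lies between the bounds set for the test. The 7-mer is present in TBX2 transcripts and not in TBX2-AS1 transcripts, and the genes that rose had z = -0.26. The genes higher in siTBX2-AS1 than in siTBX2 had the same highest 7-mer (z = 7.25, highest permutation 6.52), and the lower ones had TTAAACT (z = 19.37, highest permutation 5.76).

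Genes that rose in both knockdowns may be genes that the control siRNA silenced in siNTC. AGACGTA had z = 9.30 among the 47 searched genes, above each permutation (highest 8.71), and genes that fell in both had z = -1.42. It was also the highest 7-mer among all genes that rose in siTBX2 (z = 11.09, highest permutation 6.91, 19 of 136 genes). Among those that rose in siTBX2-AS1 the highest was GACGTAC, which shares 6 bases with it (z = 7.41, highest permutation 6.51, 14 of 295 genes). Both are in neither TBX2 nor TBX2-AS1 transcripts. Only 9 of the 47 genes carried it, so a shared response to lower TBX2 or TBX2-AS1 stays open for the others and was not tested.

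Other splits of the 6 libraries of a comparison were too few (10) for a share under 0.05. The real split called 295 genes in siTBX2 (1 of 10 splits as large, highest other 7), 840 in siTBX2-AS1 (1 of 10, highest other 4) and 1015 between the knockdowns (1 of 10, highest other 5). For gene lists, the real splits called 8 in siTBX2 (2 of 10 as large, highest other 8), 8 in siTBX2-AS1 (2 of 10, highest other 8) and 7 between the knockdowns (3 of 10, highest other 7), so other groupings of the same libraries called as many lists. For the 92 genes changed the same way in both knockdowns, 2 of 100 regroupings of the 9 libraries gave as many, a share under 0.05. The highest other, 267, took the 3 siTBX2-AS1 libraries as the control and mixed the siNTC and siTBX2 libraries in the other groups (362 and 391 calls), and the next gave 7. In 98 of the 99 others at least 1 comparison called fewer than 92 genes, so the share does not show an overlap beyond that of shared controls.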
